A study of Cupriavidus metallidurans with 16 samples.

How the data were processed

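Total RNA of Cupriavidus metallidurans was hybridised to 16 custom Agilent arrays, 1 array per sample and 1 dye (Cy3) per array, per the labels' protocols and the file headers. The samples fall into 6 groups by their titles: CH34 and 4 deletion mutants, each with the metal mix and each with 3 arrays, and 1 array of CH34 labelled only as without, which was assumed to mean without the metal mix. The labels do not say whether the replicates came from separate cultures, so the p-values measure only the spread between these arrays, which may be technical. No 2 arrays held identical values, and the highest correlation between any 2 was 0.986.

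The deposited scanner output holds spot intensity on a linear scale. The authors' files give a processed intensity per spot that Agilent Feature Extraction 10.7.3.1 had background-subtracted and detrended over the array surface, with a surrogate value for dim spots, per the file headers, and it was not normalized between arrays. The deposited files also give the mean spot intensity, the local background intensity, and yes or no marks for spots well above background, saturated or outlying. A deposited table of values per feature, the series matrix, is likewise a linear intensity with the same mean, 1.03, in every column. Its medians lie between 0.141 and 0.182, and how it was scaled and whether it was centred are not given in the sources used here. It has 9735 entries, of which 9734 were matched to features through a probe identifier. Set against the scanner values by rank correlation, each column was closest to an array of its own group (rho 0.990 to 0.996), but the 6 columns of CH34 with metals and of the rpoIJK deletion were each closest to another replicate number than their title gives. It was used only as an alternative.

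From the scanner output, log2 of the processed intensity minus the 75th percentile of each array was taken in R 4.3.3 with limma 3.58.1 and the data.table package, version 1.17.8. Control spots and 8 outlying spots were left out, and no spot was saturated on any array. Of 15743 spots, 15207 were non-control probes, and these were averaged into 10100 features, namely 6681 gene features and 3419 intergenic regions. Of the features, 4993 had 1 probe and 5107 had more. Genes called in a comparison and measured by several probes had probes moving in opposite directions in 1 of 1175 for the rpoIJK deletion, 2 of 756 for rpoQR, 0 of 1086 for rpoPE cnrH, 3 of 666 for rpoLMO and 1 of 264 for the metals. A feature was tested if it was well above background on every array of at least 1 of the 5 groups of 3, which left 6052 gene features and 2819 intergenic regions. The gene features include 315 segments of long genes and 68 structural RNA tags.

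Between 68.8% and 91.2% of the probes were well above background per array, and the 75th percentile of the processed intensity ran from 97.6 to 230. Within groups the arrays correlated at 0.961 to 0.986 over features. With 3 arrays in a group the number of arrays limits the precision.

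All groups entered 1 limma model (lmFit and eBayes, 10 residual degrees of freedom) without replicate or slide terms, and genes and intergenic regions were adjusted separately by Benjamini-Hochberg within each comparison. A gene was called changed at an adjusted p under 0.05, and every adjusted p of a single gene given here is from limma. The comparisons were each mutant against CH34, both with metals, CH34 with metals against the lone array without, and each mutant against the mean of the other 3 mutants. The lone array was assumed to vary like the other groups. Standard errors (SE) are those of limma. Where a feature was not well above background on any array of a group, a lower bound, "at least N-fold", is given beside the fitted change, which is no bound itself. That bound sets the mean of the bright group against the mean, over the dim group's arrays, of the higher of the probe's own signal and the lowest signal of any probe well above background, and it is 0 on the log2 scale where both groups are at background.

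The procedure was tested on simulated data with 200 of 6052 genes changed. It recovered 61.2%, 56.7%, 71.6% and 71.6% of the genes changed 2-fold in the rpoIJK, rpoQR, rpoPE cnrH and rpoLMO comparisons, and 22.4% in the comparison of metals with the lone array, with 10, 8, 8, 9 and 2 false calls. Genes changed 4-fold were recovered at 95.5%, 98.5%, 97.0%, 98.5% and 81.8%. The simulated noise was independent between genes and arrays, with no trend with brightness and no difference in scaling between groups. The false calls therefore do not cover calls that such a trend or the scaling could make in the real data.

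The array names 329 gene features by a symbol and 6352 by a locus tag (Rmet and a number) alone. No reference was used here that pairs tags with names, so tags are printed as the files give them. No deleted sigma factor gene appears under its symbol on the array, and without a reference their neighbours could not be identified. The level of the deleted genes could therefore not be used to check the labels. For the same reason, a tag that falls to background in 1 mutant may be a deleted gene itself. Of the gene lists fixed before the data were examined, 4 had at least 3 measured members, namely flagellar and chemotaxis genes (18 measured), ribosomal protein genes (47), heat shock and protein quality genes (6) and histidine biosynthesis genes (6). The lists of iron-sulfur cluster assembly, of sulfur assimilation with cysteine and glutathione synthesis, and of ATP synthase had 2, 1 and 1 measured members and were not tested. The lists of metal efflux, copper resistance, metal uptake, iron uptake, other metal resistance, sigma factor, envelope stress, oxidative stress, pilus, respiratory, hydrogenase and CO2 fixation genes had 0 members with a matching symbol. Those of plasmid and chromid genes could not be formed, as no reference that places genes on replicons was used. Lists were tested with limma's camera at a preset correlation of 0.01, adjusted over the lists within a comparison, with an estimated correlation and with fry as alternatives. All lists hold genes with a symbol, while camera sets them against all genes tested. Fry tests whether the genes of a list move on balance 1 way and does not compare them with other genes. Intergenic regions, whose names in the files include the replicon, were grouped by replicon.

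The genes named were to be, per comparison with CH34, the 12 largest rises and 12 largest falls among called genes with at least 2-fold change and no overlap between the arrays of both groups, 5 each way for comparisons between mutants, and up to 4 members of each list. Since most genes carry only a tag, the rule was applied once to all identifiers and once to genes with a symbol, of which 304 are not segments. That adaptation was made after the files had been seen, and at most 2 tags each way are printed per comparison.

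The alternatives fixed before the data were examined were normexp background correction of the mean and background intensity with an offset of 50, quantile and median scaling, no filter and a filter on all 16 arrays, replicate number, slide as a fixed or random block, only the compared groups in the model, eBayes with trend and robust, the brightest probe per gene, the series matrix, at least 2-fold change, and leaving out each array in turn. The array of rpoQR replicate 3 has 9 spots whose local background lies above their signal, up to 74403, and normexp with all spots gave that array a median of 710 against 86.3 to 129 on the others. A second normexp correction without those spots was therefore added after the data had been seen, as were cyclic loess, the array row on the slide, merged gene segments, removal of the 2 tag intervals described in the results, replicate numbers in the order of the series matrix, and lists assembled from the symbols on the array. Here "normexp" means the correction with all spots, and "normexp without the speck" the second one. The corrections differ on that array alone, but its values enter the pooled spread, and so the calls, of every comparison. The arrays lie on 2 slides of 8, each with arrays of all 5 strains, so slide effects can be told from strain effects. The array without metals lies on slide 2. Values within a slide rest on 1 or 2 arrays of each strain, with the spread pooled over the strains that have 2 arrays there (3 residual degrees of freedom on slide 1 and 2 on slide 2), and they are given as values only. All 3 rpoLMO arrays lie in row 1 of the slides and all 3 rpoPE cnrH arrays in row 2, and the other strains have arrays in both.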

Results

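Transcript levels were measured in Cupriavidus metallidurans CH34, a bacterium known for its resistance to transition metals, and in 4 derivatives lacking genes of extracytoplasmic function sigma factors. Such sigma factors are subunits of RNA polymerase that direct it to particular promoters. The derivatives lacked rpoI, rpoJ and rpoK (the rpoIJK deletion), rpoQ and rpoR (rpoQR), rpoP, rpoE and cnrH (rpoPE cnrH), or rpoL, rpoM and rpoO (rpoLMO). Cultures in a mineral salts medium with 0.2% gluconate were given cobalt, nickel, zinc, cadmium and copper, 30 µM of each, at a turbidity of 100 Klett, and cells were collected 10 min later. Each of the 5 strains was measured with metals on 3 arrays, and CH34 without on 1 array. The title of that lone array says only "without", and reading it as without the metal mix is an assumption behind every value for metals. The share of probes well above background was 71.3% to 80.3% in CH34 with metals, 77.5% to 85.0% in the rpoIJK deletion, 83.5% to 91.2% in rpoQR, 79.5% to 88.1% in rpoPE cnrH, 70.1% to 71.4% in rpoLMO and 68.8% on the array without metals. All changes below are log2 differences of processed signal scaled to the 75th percentile of each array.

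CH34 with metals was compared with CH34 without to describe the response of the parent to the metals. Genes of the flagellum, the rotating filament that drives swimming, were lower with metals. Of 18 measured flagellar genes 11 fell and 7 did not pass the test (15 fell when adjusted over the list alone). The mean change of the list was −1.59 (camera adjusted p = 1.16e-11, and adjusted p = 0.0337 with an estimated correlation). The rod gene flgB changed by −2.69 ± 0.37 (SE, adjusted p = 0.000184) and flgD, which encodes the hook cap, by −2.61 ± 0.36 (adjusted p = 0.000201), 3 arrays against 1 in each case. The rod gene flgF fell as well (adjusted p = 0.00202). The genes fliF, flhB, flgG, flgE, fliG and fliH fell by 1.34, 1.96, 1.98, 2.06, 2.08 and 2.16. Ribosomal protein genes were lower as well, with 6 of 47 falling and 41 not passing (16 when adjusted over the list alone, 32 at an unadjusted p under 0.05). Their mean was −0.62 (adjusted p = 5.27e-12, and adjusted p = 0.119 with an estimated correlation). Among them rplF, a protein of the large subunit, changed by −0.87 ± 0.17 (adjusted p = 0.00489).

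The genes pstC and pstA, both encoding membrane subunits of the phosphate transporter, rose in the same comparison, by 1.13 ± 0.23 (adjusted p = 0.00608) and 1.12 ± 0.27 (adjusted p = 0.0162). The gene proA, of proline synthesis, was called higher (adjusted p = 0.0109, at least 1.17-fold), but its sign turned under both normexp corrections (−0.05). Of 6 heat shock and protein quality genes, which include the chaperonin genes groEL and groES, 0 passed over all genes, 2 rose when adjusted over the list alone and 3 had an unadjusted p under 0.05 (limma). The mean of that list was +0.54 (adjusted p = 0.023, and adjusted p = 0.119 with an estimated correlation). Its call was lost without CH34 replicate 3 (adjusted p = 0.0591). Of the 6 histidine biosynthesis genes 0 passed in limma, 0 at an unadjusted p under 0.05, with a mean of +0.18 (adjusted p = 0.328 in camera, 0.0219 in fry). Most genes that moved carry only a tag. Rmet_4596 rose by 10.14 ± 0.28 (adjusted p = 2.94e-11, at least 490-fold) and Rmet_5969 by 7.64 ± 0.36 (adjusted p = 2.92e-09), while Rmet_4565 changed by −4.85 ± 0.32 (adjusted p = 9.96e-08). Changed tags lay side by side. There were 17 runs of at least 5 neighbouring tags called in 1 direction, against 0 in 100 shuffles of the tag order, and the longest held 18 neighbouring tags with a median of +3.72.

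In all, 582 of 6052 genes changed with metals, 316 higher and 266 lower, and 461 of them at least 2-fold (252 higher, 209 lower). With slide as a block 629 genes were called. Within slide 2, which holds the array without metals and 1 array of CH34 with metals, 330 were, a count with 1 array on each side. The means of the flagellar, ribosomal, heat shock and histidine lists were −1.51, −0.67, +0.66 and +0.22 with slide as a block and −1.63, −0.73, +0.58 and +0.15 within slide 2. The count was 360 with only the compared arrays in the model and 133 with normexp (86 higher, 47 lower). With normexp without the speck the split turned to 193 higher and 231 lower. Under normexp the calls of flhB, flgG, flgE, fliG, fliH and rplF were lost. The pstC and pstA calls were lost under 4 and 5 of 16 alternative settings, both normexp corrections and the series matrix among them in each case.

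The rpoIJK deletion was compared with CH34, both with metals, to find genes whose level depended on RpoI, RpoJ and RpoK. Flagellar genes were lower in the mutant, with 9 of 18 falling and 9 not passing (9 when adjusted over the list alone). Their mean was −0.81 (adjusted p = 0.00112, and adjusted p = 0.208 with an estimated correlation). The genes flgD, flgF and flgB changed by −1.76 ± 0.26 (adjusted p = 0.000181), −1.68 ± 0.25 (adjusted p = 0.000229) and −1.30 (3 arrays against 3). The hook gene flgE changed by −2.22 ± 0.27 (adjusted p = 5.35e-05) and was above background on 1 of the 3 mutant arrays. Genes of histidine synthesis fell together, 5 of 6 over all genes and 5 when adjusted over the list alone, with a mean of −0.57 (adjusted p = 0.0051, and adjusted p = 0.0455 with an estimated correlation). Its first enzyme, encoded by hisG, changed by −0.93 ± 0.16 (adjusted p = 0.000451) and hisD, encoding the last, by −0.75 ± 0.15 (adjusted p = 0.00154). The member hisE lost its call without any of the 3 CH34 arrays or without rpoIJK replicate 2 or 3 (adjusted p up to 0.151). Genes with a symbol leaned lower as a class, 104 of 304 called lower and 29 higher here. In rpoQR 63 were lower and 17 higher, in rpoPE cnrH 95 and 22, and in rpoLMO 27 and 27. Over all genes more were called higher than lower in rpoIJK, rpoQR and rpoPE cnrH. The lists were not tested against that class.

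In the same mutant 4 of 6 heat shock genes fell (5 passed when adjusted over the list alone, 1 of them higher). Among them groEL changed by −1.01 ± 0.19 (adjusted p = 0.000962), groES by −1.05 ± 0.28 (adjusted p = 0.00919) and hfq, an RNA chaperone gene, by −0.63 ± 0.15 (adjusted p = 0.00518). The call of the member clpX was lost without replicate 1 or 3 of either strain (adjusted p up to 0.102). The list's mean was −0.50, and camera did not call it (adjusted p = 0.0551) while fry did (adjusted p = 0.0032). It was called with slide as a block (adjusted p = 0.0414) and without CH34 replicate 1 or rpoIJK replicate 2 (adjusted p down to 0.0315). Ribosomal protein genes went both ways, 3 higher and 6 lower of 47 (2 higher and 1 lower when adjusted over the list alone). Their mean was −0.14 (adjusted p = 0.0551), and it was +0.11 with cyclic loess. The list was called without CH34 replicate 2 or rpoIJK replicate 3 (adjusted p down to 0.0213) and with median scaling (adjusted p = 0.0297). The higher members included rplN at +0.90 and rplX at +0.88. Other genes that rose were cobS (+1.79 ± 0.36, adjusted p = 0.00156), of cobalamin synthesis, pyrF (+1.02 ± 0.19, adjusted p = 0.000807), of pyrimidine synthesis, and mtgA (+1.17 ± 0.23, adjusted p = 0.00143), a peptidoglycan glycosyltransferase gene. The genes ispD (+1.00 ± 0.14), phnH (+1.15 ± 0.24) and rdgC (+1.13 ± 0.23) rose too. Among falling genes were sucC, a subunit of succinyl-CoA synthetase (−1.14 ± 0.19, adjusted p = 0.00051), acpS (−1.10 ± 0.17), queA (−1.10) and tolB (−1.07 ± 0.28). Of the tags, Rmet_4002 rose by 7.57 ± 0.22 (adjusted p = 2.86e-11) and Rmet_4500 by 6.96 ± 0.16 (adjusted p = 2.54e-12, at least 40.3-fold).

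For the rpoIJK deletion 2398 of 6052 genes were called, 1353 higher and 1045 lower, 871 of them at least 2-fold (667 higher, 204 lower). The mutant and CH34 arrays did not overlap for 2998 genes (49.5%, where chance gives 10%). The split by direction depended on the scaling and was 943 higher and 1728 lower with median scaling, 936 and 1183 with quantile normalization, and 666 and 891 with normexp without the speck. With slide as a block 2465 genes were called, with 894 within slide 1 (1 mutant array against 2 of CH34) and 783 within slide 2 (2 against 1). Over the same 3 settings the flagellar mean was −0.85, −0.78 and −0.79, the histidine mean −0.59, −0.61 and −0.53, the heat shock mean −0.56, −0.74 and −0.42, and the ribosomal mean −0.12, −0.26 and −0.00. Normexp left 261 genes (166 higher, 95 lower) and, of the genes with a symbol named for this mutant, only the calls of flgD, flgF and flgB. The 2 normexp corrections differ on 1 rpoQR array alone and gave rpoIJK the same median change, 0.0048. Calls lost with normexp but kept without the speck were thus lost through the pooled spread. This does not cover every lost call, since normexp without the speck also called fewer genes, 1557 against 2398. Over the alternative settings the change of phnH went down to 0.28, and its call was lost in 2 of 17.

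The comparison of the rpoQR deletion with CH34 asked the same of RpoQ and RpoR. Here 9 of 18 flagellar genes fell and 9 did not pass (13 fell when adjusted over the list alone). The mean was −0.84 (adjusted p = 7.03e-07, and adjusted p = 0.0651 with an estimated correlation). Among them flgH, of the outer ring, changed by −1.31 ± 0.29 (adjusted p = 0.00577), flgD by −1.28 ± 0.26 (adjusted p = 0.0029), flgB by −1.10 ± 0.26 (adjusted p = 0.00757) and flgF by −1.07 ± 0.25 (adjusted p = 0.00784). Histidine genes changed by −0.39 on average, 2 of 6 falling and 3 when adjusted over the list alone (adjusted p = 0.0127, and adjusted p = 0.0651 with an estimated correlation). The members that fell were hisD at −0.67 (adjusted p = 0.00569) and hisG at −0.69 (adjusted p = 0.00597). The heat shock list had a mean of −0.51 with 3 of 6 falling, and 3 when adjusted over the list alone (adjusted p = 0.0127, and adjusted p = 0.0902 with an estimated correlation). Its 3 called members each lost the call without some single array. For hfq this was CH34 replicate 3 (adjusted p = 0.056), for groEL replicate 3 of either strain (adjusted p up to 0.0591), and for groES CH34 replicate 2 or 3 or any rpoQR array (adjusted p up to 0.156). Of 47 ribosomal protein genes 1 was higher and 2 were lower, and 0 passed in limma when adjusted over the list alone (3 higher and 5 lower at an unadjusted p under 0.05). Their mean was −0.09 (adjusted p = 0.0591), with the sign turned under normexp without the speck (+0.02), cyclic loess (+0.04) and quantile normalization (+0.00). The list was called without CH34 replicate 2 or rpoQR replicate 3 (adjusted p down to 0.0177) and with median scaling (mean −0.23, adjusted p = 0.0304). Normexp called it lower (mean −0.43, adjusted p = 1.82e-09), and normexp without the speck called it at +0.02 (adjusted p = 0.00515).

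Outside the lists, pyrF rose by 1.14 ± 0.19 (adjusted p = 0.000817) in the rpoQR deletion. The gene gatC, for a subunit of an amidotransferase acting on charged tRNA, measured +1.73 ± 0.20 (adjusted p = 3.84e-05, at least 1.69-fold), a sign that turned under normexp without the speck (−0.08). Of the tags, Rmet_4682 and Rmet_4684 rose by 4.47 ± 0.36 (adjusted p = 7.14e-07, at least 9.20-fold) and 4.42 ± 0.30 (adjusted p = 1.28e-07, at least 21.2-fold), and their near neighbour Rmet_4686 changed by −9.41 ± 0.14 (adjusted p = 3.74e-15, at least 205-fold lower). Whether Rmet_4686 is a deleted gene could not be checked. The test called 1570 of 6052 genes, 995 higher and 575 lower, 578 of them at least 2-fold (437 higher, 141 lower). The arrays did not overlap for 2706 genes (44.7%, where chance gives 10%). Without rpoQR replicate 3 the count was 991. The split was 709 higher and 956 lower with median scaling, 638 and 604 with quantile normalization, 674 and 662 with cyclic loess, and 433 and 857 with normexp without the speck. With slide as a block 1614 genes were called, with 775 within slide 1 (2 arrays against 2) and 163 within slide 2 (1 against 1). Over the same 3 settings the flagellar mean was −0.84, −0.98 and −0.56, the histidine mean −0.39, −0.45 and −0.26, the heat shock mean −0.51, −0.54 and −0.46, and the ribosomal mean −0.09, −0.16 and +0.04. Normexp left 42 genes and none of the calls on symbol-bearing genes given here for rpoQR. The heat shock list lost its call with normexp without the speck, the series matrix and cyclic loess (adjusted p = 0.171, 0.0718 and 0.0616), the histidine list with normexp (adjusted p = 0.107).

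The rpoPE cnrH deletion lacks, besides rpoP and rpoE, the sigma factor gene cnrH of the cobalt and nickel efflux determinant cnr. The largest rises among genes with a symbol were those of rbcL and pgk__2. The gene rbcL, for the large subunit of the carbon-fixing enzyme ribulose bisphosphate carboxylase, rose by 6.29 ± 0.25 (adjusted p = 2.14e-10, at least 16.8-fold) from a level not well above background on any of the 3 CH34 arrays. The phosphoglycerate kinase gene pgk__2 rose by 3.42 ± 0.33 (adjusted p = 2.38e-06). These sizes and the bound hold for the processed signal, and under both normexp corrections rbcL rose by 1.97 and pgk__2 by 1.52. Flagellar genes were lower, with 12 of 18 falling and 6 not passing (14 fell when adjusted over the list alone). Their mean was −1.16 (adjusted p = 5.41e-06, and adjusted p = 0.0883 with an estimated correlation), and members included flgG (−2.22 ± 0.33, adjusted p = 0.000189), flgD (−2.05 ± 0.26, adjusted p = 3.4e-05) and flgF (−1.91, adjusted p = 6.06e-05). The call of flgJ was lost without CH34 replicate 1 or 2 or rpoPE cnrH replicate 3 (adjusted p up to 0.0803). Histidine genes had a mean of −0.71 with 3 of 6 falling, 5 when adjusted over the list alone (adjusted p = 0.00249, and adjusted p = 0.0316 with an estimated correlation). Members included hisD at −1.05 (adjusted p = 0.000131) and hisB at −0.78 ± 0.13 (adjusted p = 0.000516). Among heat shock genes 5 of 6 fell, and 5 when adjusted over the list alone, with a mean of −0.76 (adjusted p = 0.00908, and adjusted p = 0.0883 with an estimated correlation), hfq lying at −1.15 ± 0.15 (adjusted p = 6.42e-05) and groEL at −1.13 ± 0.19 (adjusted p = 0.00047). The member hslU lost its call without replicate 2 or 3 of either strain (adjusted p up to 0.174).

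Of 47 ribosomal protein genes 6 fell in the rpoPE cnrH deletion and 41 did not pass (0 when adjusted over the list alone in limma, 13 lower at an unadjusted p under 0.05). Their mean was −0.25 (adjusted p = 0.0038, and adjusted p = 0.444 with an estimated correlation), with the sign turned under cyclic loess (+0.02) and the call lost without rpoPE cnrH replicate 1 (adjusted p = 0.216). Further genes that fell were alr (−1.44 ± 0.14, adjusted p = 2.07e-06), for alanine racemase of cell wall synthesis, hemH (−1.38 ± 0.16, adjusted p = 1.32e-05), for ferrochelatase of heme synthesis, and tolB (−1.68 ± 0.28, adjusted p = 0.000385), for a periplasmic protein of the envelope. The gene pyrF rose by 1.85 ± 0.19 (adjusted p = 3.98e-06), mtgA by 1.65 ± 0.23 (adjusted p = 0.000101), phnH by 1.35 (adjusted p = 0.000729), ampG by 1.15 ± 0.20 (adjusted p = 0.00059) and dnaE2 by 1.15 ± 0.14 (adjusted p = 3.01e-05). Among tags without a symbol, a run of 57 neighbours from Rmet_1484 to Rmet_1547 rose, with a median of +4.82, and was the longest of 60 runs of at least 5 tags (1.97 on average in 100 shuffles). Of these 57 tags 23 were at background in CH34, the median was 3.52 with those at their bound, and under other scalings it lay between 1.49 and 4.66. The largest falls were those of Rmet_2425 (−5.85 ± 0.20, adjusted p = 1.12e-10, a log2 fall of at least 3.91) and Rmet_5846 (−5.59 ± 0.23, adjusted p = 3.28e-10, at least 12.4-fold lower). Whether either tag is a deleted gene could not be checked.

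For the rpoPE cnrH deletion 2215 of 6052 genes were called, 1180 higher and 1035 lower, 858 of them at least 2-fold (599 higher, 259 lower), and the arrays did not overlap for 3034 genes (50.1%, where chance gives 10%). The split was 896 higher and 1510 lower with median scaling, 896 and 1182 with quantile normalization, and 576 and 1075 with normexp without the speck. With slide as a block 2273 genes were called, with 720 within slide 1 (1 mutant array against 2 of CH34) and 767 within slide 2 (2 against 1). With array row as a block, all 3 arrays of this mutant lying in row 2, the count was 1892. The flagellar mean with slide as a block and within slides 1 and 2 was −1.20, −1.07 and −1.17, the histidine mean −0.73, −0.79 and −0.65, the heat shock mean −0.82, −0.96 and −0.69, and the ribosomal mean −0.22, −0.14 and −0.22. Normexp left 371 genes and ended the calls of mtgA, phnH, ampG, dnaE2 and groEL, but not those of rbcL, pgk__2, pyrF, alr, hemH, tolB, hfq, hisD, hisB, flgG, flgD and flgF. The heat shock list lost its call with both normexp corrections and cyclic loess (adjusted p = 0.0652, 0.0685 and 0.0523). The ribosomal list lost its call with these 3, quantile normalization and the series matrix (adjusted p = 0.445, 0.507, 0.737, 0.566 and 0.0837).

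The comparison of the rpoLMO deletion with CH34 asked which genes depended on RpoL, RpoM and RpoO. Ribosomal protein genes were higher in this mutant, with 7 of 47 rising, 7 when adjusted over the list alone and 18 at an unadjusted p under 0.05. Their mean was +0.33 (adjusted p = 2.15e-06, and adjusted p = 0.331 with an estimated correlation). The gene rpsL, of the small subunit, rose by 0.81 ± 0.20 (adjusted p = 0.0109), rpsI by 0.73 ± 0.16 (adjusted p = 0.00512) and rpmI, of the large subunit, by 0.53 (adjusted p = 0.00835). Camera did not call the flagellar, histidine and heat shock lists here, while fry called the histidine and heat shock lists lower (adjusted p = 0.000448 and 0.0237). The flagellar mean was −0.11 with 1 of 18 falling and 1 when adjusted over the list alone (adjusted p = 0.635). The histidine mean was −0.27 with 1 of 6 falling and 2 when adjusted over the list alone (adjusted p = 0.161), and the heat shock mean was −0.34 with 1 of 6 falling and 1 when adjusted over the list alone (adjusted p = 0.161). The falling members, hisG, hfq and flhB, lost their calls in other settings. Those of hisG (adjusted p up to 0.0785) and hfq (adjusted p up to 0.158) were lost without any of the 3 CH34 arrays or without rpoLMO replicate 2 or 3, and that of flhB under 5 of 17 alternative settings. Of single genes with a symbol, gatC rose by 1.77 ± 0.20 (adjusted p = 3.5e-05, at least 1.73-fold), but by 0.22 under both normexp corrections (adjusted p = 1 and 0.16). The gene mdoG__2, of periplasmic glucan synthesis, changed by −1.16 ± 0.23 (adjusted p = 0.00341), and phhA, for phenylalanine hydroxylase, by −1.65 ± 0.49 (adjusted p = 0.0283). The phhA call was lost without CH34 replicate 1 or 2 or rpoLMO replicate 1 or 2 (adjusted p up to 0.103). Of the tags, Rmet_0599 rose by 5.16 ± 0.14 (adjusted p = 2.25e-11) and Rmet_3282 by 4.89 ± 0.24 (adjusted p = 4.07e-09), the latter above background on 1 of the 3 CH34 arrays.

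The rpoLMO deletion differed from CH34 in 1351 of 6052 genes, 609 higher and 742 lower, 444 of them at least 2-fold (163 higher, 281 lower), and the arrays did not overlap for 2523 genes (41.7%, where chance gives 10%). The count was 816 without CH34 replicate 3, 759 with normexp without the speck (423 higher, 336 lower) and 43 with normexp (28 higher, 15 lower). Under normexp the calls of rpsL, rpsI, rpmI and mdoG__2 were lost. With median scaling 817 were higher and 549 lower. With array row as a block, all 3 arrays of this mutant lying in row 1, it was 918. With slide as a block 1412 genes were called, with 355 within slide 1 (2 arrays against 2) and 189 within slide 2 (1 against 1). The ribosomal mean with slide as a block and within slides 1 and 2 was +0.33, +0.32 and +0.37, the flagellar mean −0.11, −0.31 and +0.29, the histidine mean −0.27, −0.31 and −0.20, and the heat shock mean −0.34, −0.32 and −0.39. Over all genes the median change was between −0.03 and 0.09 in the 5 comparisons with CH34. It moved by more than 0.1 for rpoIJK, rpoQR and rpoPE cnrH, to −0.15, −0.06 and −0.14 with median scaling, and was −0.08 for both rpoIJK and rpoPE cnrH with quantile normalization. With normexp without the speck it was −0.13 for rpoQR and −0.11 for rpoPE cnrH.

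**Figure D1:**
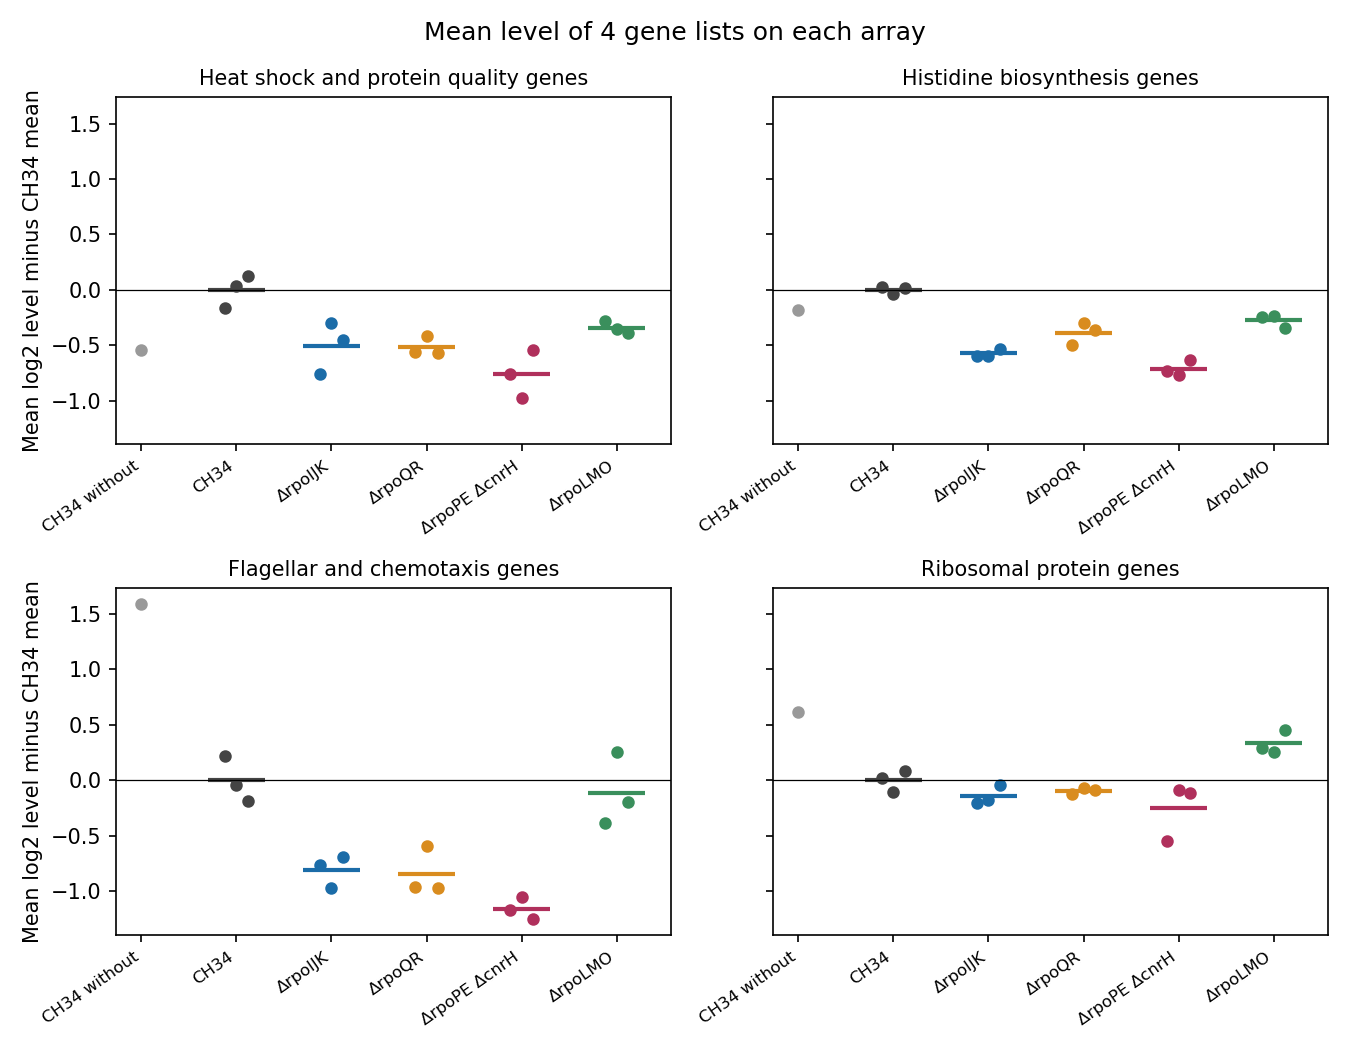
Mean log2 level of the genes of 4 lists on each array (points), relative to the mean of CH34 with metals, for CH34 and the 4 mutants with metals (3 arrays each, bar at the group mean) and the 1 array without metals (grey). The flagellar mean lies at −0.81, −0.84 and −1.16 in the rpoIJK, rpoQR and rpoPE cnrH deletions and at −0.11 in rpoLMO, and the ribosomal mean lies at +0.33 in rpoLMO.

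Many genes were called in the same direction in several mutants. In all 4 mutants 125 genes were higher, among them gatA, gatB and gatC, which encode the 3 subunits of an amidotransferase, and 128 were lower. The 12 of these with a symbol were hisG and hfq, alr, ddl and murD of cell wall synthesis, lolA of lipoprotein transport, ispH__1 and ispH__2 of isoprenoid synthesis, acpS, nadE, trmU and ntpA. The rise of gatC did not hold under normexp without the speck in any mutant (log2 changes 0.11, −0.08, 0.01 and 0.22), and the rpoLMO calls of hisG and hfq were lost without single arrays (adjusted p up to 0.0785 and 0.158). At least 2 mutants shared the direction of 2073 genes, against a mean of 0.01 and a highest value of 1 in 100 simulations of unchanged groups that share the CH34 arrays. With no gene changed hardly any gene is called, so the low overlap in the simulations was fixed in advance. It does not show how much overlap the shared arrays make once many genes change. The rpoIJK and rpoQR deletions shared 808 higher and 449 lower genes (222 and 99.3 for independent lists) and had opposite calls for 4. The rpoIJK and rpoPE cnrH deletions shared 788 and 637 (264 and 179) with 59 opposite, and rpoQR and rpoPE cnrH 732 and 423 (194 and 98.3) with 40 opposite. The rpoLMO deletion shared 186 and 281 with rpoIJK (136 and 128), 194 and 230 with rpoQR (100.1 and 70.5), and 223 and 238 with rpoPE cnrH (119 and 127), with 254, 186 and 192 opposite calls.

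Across genes, which are not independent replicates, the changes in the rpoIJK and rpoQR deletions correlated at 0.83 with a covariance of 0.557, where the simulation gave 0.50 and 0.034. The covariance was 0.303 for rpoIJK with rpoPE cnrH, 0.281 for rpoQR with rpoPE cnrH, 0.218 for rpoIJK with rpoLMO and 0.259 for rpoQR with rpoLMO, against about 0.034 in simulation, and 0.0262 for rpoPE cnrH with rpoLMO against 0.0342. Correlations in that order were 0.38, 0.39, 0.36, 0.46 and 0.04, all below the 0.50 that the simulation gave for each pair, rounded. Without the 2 tag intervals described further on, these correlations were 0.59, 0.67, 0.02, 0.09 and 0.17, and that of rpoIJK with rpoQR was 0.74, with no simulation run for these. The 3 CH34 arrays cannot be split into parts of at least 2, so part of the excess in shared calls may come from the shared controls.

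Comparing each mutant with the mean of the other 3 avoided the shared CH34 arrays. These comparisons share the mutant arrays instead, and a group that stands apart, such as rpoLMO, enters the reference of each other mutant. In the rpoLMO deletion, ribosomal protein genes were higher than in the others, 28 of 47 rising and 1 falling (30 and 1 when adjusted over the list alone). The mean was +0.50 (adjusted p = 3.45e-08, and adjusted p = 0.206 with an estimated correlation). Flagellar genes were higher too, 13 of 18 rising and 1 falling (15 and 1 when adjusted over the list alone). The mean was +0.82 (adjusted p = 3.58e-05, and adjusted p = 0.15 with an estimated correlation). The ribosomal gene rpsS changed by +1.73 ± 0.29 (adjusted p = 0.000251), rpsR by +1.24 and the protein export gene secD by +1.29 ± 0.13 (adjusted p = 2.58e-06). In contrast pyrF changed by −2.13 ± 0.15 (adjusted p = 1.78e-07) and mdoG__2 by −2.01 ± 0.19 (adjusted p = 1.85e-06). Heat shock and histidine genes of rpoLMO were not called as lists by camera (3 of 6 and 2 of 6 rising, the same when adjusted over the list alone, adjusted p = 0.209 and 0.0698), though the histidine list was with quantile normalization (adjusted p = 0.0402). Fry called both higher (adjusted p = 0.0412 and 7.13e-05). The tag Rmet_2349 changed by −5.13 ± 0.36 (adjusted p = 1.69e-07, at least 12.2-fold lower) in rpoLMO, and Rmet_0599 by +4.74.

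In the rpoPE cnrH deletion rbcL was higher by 6.28 ± 0.20 (adjusted p = 8.46e-12, at least 18.1-fold) than in the other mutants, where it was at background on all 9 arrays. The gene pgk__2 was higher by 4.15 ± 0.27 (adjusted p = 1.97e-08) and pyrF by 1.40 (adjusted p = 7.42e-06). Under normexp rbcL was higher by 1.91 and pgk__2 by 1.57. Flagellar genes were lower, 7 of 18 falling and 1 rising (9 and 1 when adjusted over the list alone), with a mean of −0.57 (adjusted p = 0.000656, and adjusted p = 0.238 with an estimated correlation). Ribosomal protein genes were lower there as well, 6 of 47 falling (0 in limma when adjusted over the list alone, 19 at an unadjusted p under 0.05) with a mean of −0.28 (adjusted p = 4.93e-05, and adjusted p = 0.27 with an estimated correlation). The call was lost without rpoPE cnrH replicate 1 (adjusted p = 0.105) and with normexp (adjusted p = 0.934). Relative to CH34 the ribosomal mean was −0.55, −0.09 and −0.11 on rpoPE cnrH replicates 1, 2 and 3. It was −0.14 in rpoIJK, −0.09 in rpoQR and +0.33 in rpoLMO, so part of this difference comes from the rpoLMO arrays in the reference. Camera did not call the histidine and heat shock lists in rpoPE cnrH (adjusted p = 0.0565 and 0.103), but did call both without rpoPE cnrH replicate 3 and the histidine list also without rpoQR replicate 1 (adjusted p down to 0.0307). Fry called both lower (adjusted p = 4.02e-05 and 0.012). The rpoIJK deletion was higher than the others for cobD (+1.09 ± 0.14, adjusted p = 6.81e-05), of cobalamin synthesis, and pdxA__2 (+1.04 ± 0.11, adjusted p = 1.38e-05), of vitamin B6 synthesis, both calls lost with normexp. Rmet_4002 lay at +7.38 and Rmet_1120 at −3.27 ± 0.13 (adjusted p = 6.86e-10, at least 2.25-fold lower), and whether Rmet_1120 is a deleted gene could not be checked. Fry called the histidine list lower in rpoIJK (adjusted p = 0.0335). Camera called no fixed list there (adjusted p from 0.0954 to 0.916), except the ribosomal list without rpoIJK replicate 3 or rpoPE cnrH replicate 1 (adjusted p down to 0.00224) and with normexp without the speck (adjusted p = 5.44e-05). In the rpoQR deletion Rmet_4686 lay at −9.24 ± 0.11 from the others (at least 183-fold lower). The ribosomal list there had a mean of −0.07 (adjusted p = 0.0471, and adjusted p = 0.688 with an estimated correlation), with a value of −0.44 under normexp, the sign turned under normexp without the speck (+0.01) and 0 of 47 genes passing in limma (1 higher and 4 lower at an unadjusted p under 0.05). That call was lost without rpoIJK replicate 3, rpoQR replicate 1, rpoPE cnrH replicate 2 or 3, or rpoLMO replicate 3 (adjusted p up to 0.262), and with cyclic loess and quantile normalization (adjusted p = 0.0909 and 0.287). Camera did not call the flagellar, histidine and heat shock lists in rpoQR (adjusted p = 0.0715, 0.388 and 0.864), except the flagellar list without rpoIJK replicate 2, rpoQR replicate 2 or rpoLMO replicate 1 (adjusted p down to 0.0145) and the heat shock list with normexp (adjusted p = 0.0235). Fry called the histidine list higher there (adjusted p = 0.0232).

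Against the other 3 mutants 2816 genes were called in rpoLMO (1211 higher, 1605 lower, 942 at least 2-fold), 1785 in rpoIJK (951 and 834, 441), 1141 in rpoPE cnrH (632 and 509, 441) and 546 in rpoQR (328 and 218, 216). With slide as a block the counts were 2840, 1777, 1195 and 575, within slide 1 they were 1616, 156, 373 and 227, and within slide 2 they were 1081, 1226, 690 and 84, each mutant having 1 or 2 arrays on a slide. With array row as a block they were 1928, 1545, 671 and 490. All 3 rpoLMO arrays lay in row 1 and all 3 rpoPE cnrH arrays in row 2, so for these 2 mutants row and strain are partly confounded. Without rpoIJK replicate 2 the rpoIJK count was 960, without rpoPE cnrH replicate 2 the rpoPE cnrH count was 757, and the rpoQR count was 285 without rpoQR replicate 3 and 358 without rpoQR replicate 1. The split for rpoLMO turned to 2318 higher and 1135 lower with median scaling, 1483 and 1042 with quantile normalization, and 1329 and 687 with normexp without the speck. For rpoIJK it was 665 and 1429 with median scaling, 738 and 991 with quantile normalization, and 148 and 63 with normexp. In rpoPE cnrH median scaling gave 556 and 701, and in rpoQR the split was 213 and 242 with cyclic loess, 269 and 499 with normexp without the speck, and 4 and 22 with normexp.

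Signal was lost over 2 stretches of tags in 3 of the mutants. Of 74 consecutive tags from Rmet_1264 onwards, 60 were well above background on all CH34 arrays with metals and 56 in the rpoPE cnrH deletion, but 36 of them, above background in rpoPE cnrH, were not so on any array of the rpoIJK, rpoQR and rpoLMO deletions. The median changes of the stretch were −2.97, −3.41 and −2.90 in these 3 mutants (−1.62, −2.09 and −1.58 with tags at background at their bound) and −0.14 in rpoPE cnrH. The other stretch comprised 22 tags inside the run that rose in rpoPE cnrH, where 19 were above background in CH34 and 12 were at background in the same 3 mutants, with medians of −3.51, −3.69 and −3.58 (−1.88, −2.47 and −1.66 with tags at their bound), and +5.94 in rpoPE cnrH. In the flanks of each stretch 0 of 10 tags were lost in any of the 3 mutants. A nearby tag lost in all 3 but not in rpoPE cnrH would have been joined to the stretch, so the edges are partly set by definition. All 48 tags above background on every CH34 array, at background on every array of these 3 mutants and above background on at least 1 rpoPE cnrH array lay in the 2 stretches, as did Rmet_1286, singled out after its values had been seen, which was at background in rpoPE cnrH too. Of 5152 genes above background in CH34, 165 were at background in rpoLMO, 63 in rpoIJK, 53 in rpoQR and 12 in rpoPE cnrH. Of these, 77, 2, 1 and 7 were above background on every array of the other 3 mutants. Deleted genes may be among them, which could not be checked.

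**Figure D2:**
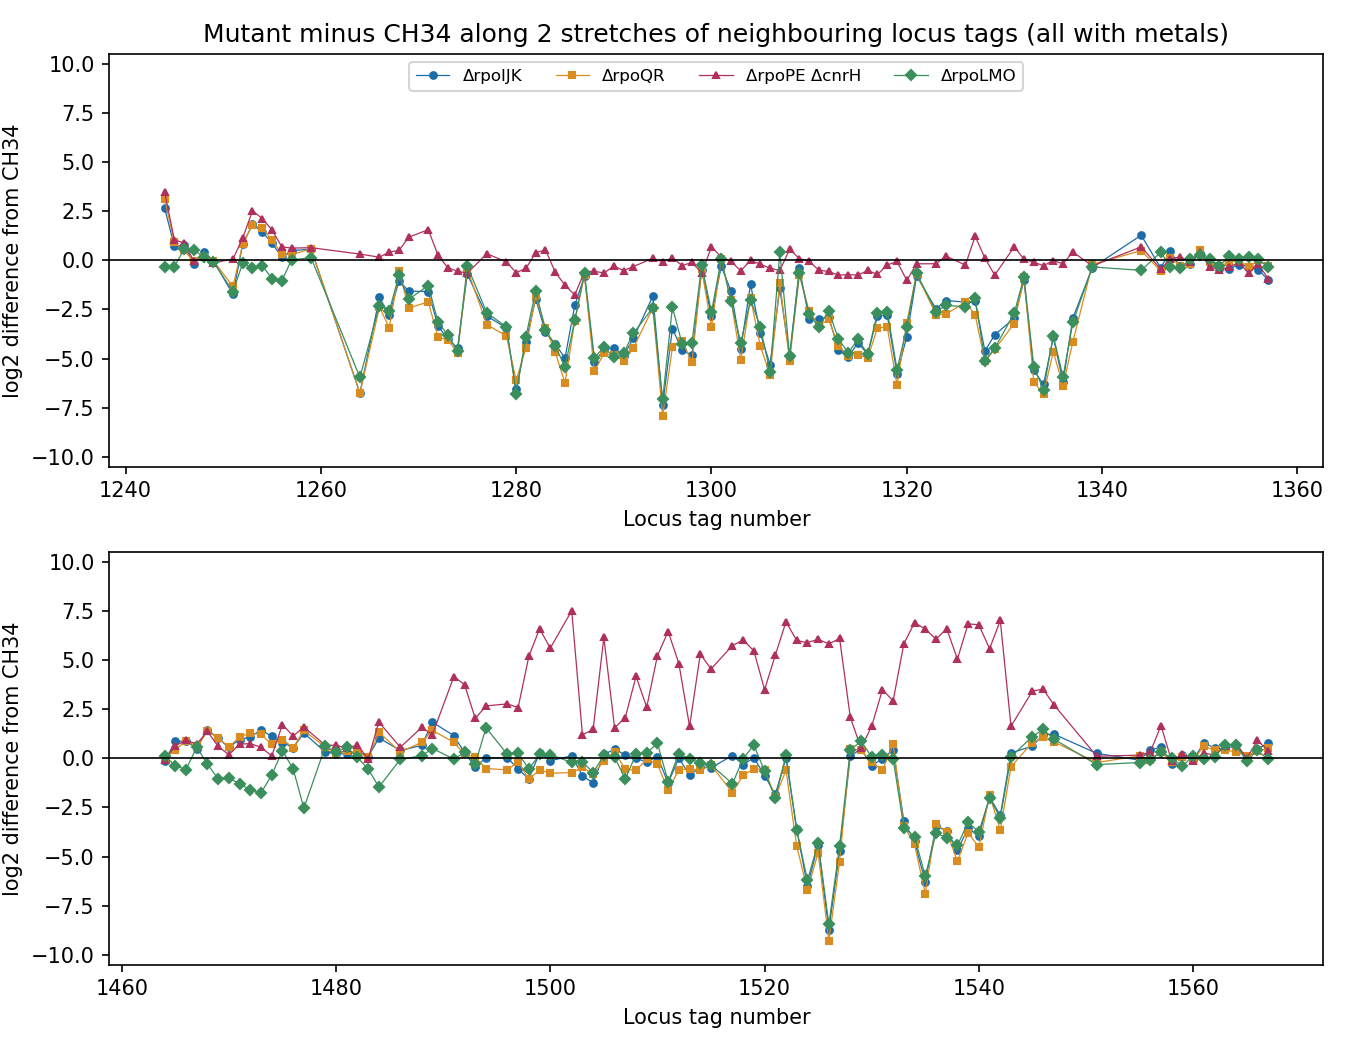
Log2 difference from CH34 (vertical axis) against locus tag number (horizontal axis) for the 4 mutants, all with metals, in the 2 regions that hold the stretches at background, 1 point per tag (joined by lines) as the mean of 3 arrays against 3. Over the stretch of 74 tags the medians are −2.97, −3.41 and −2.90 in the rpoIJK, rpoQR and rpoLMO deletions and −0.14 in rpoPE cnrH, and over the 22 tags they are −3.51, −3.69, −3.58 and +5.94.

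Intergenic regions were tested as a family of their own. With metals 223 of 2819 changed in CH34 (133 higher, 90 lower), and the regions of plasmid pMOL30, which carries several metal resistance determinants, were higher as a group. Of 136 tested regions on this plasmid 33 rose, 30 of them at least 2-fold, and 0 fell in limma (2 lower at an unadjusted p under 0.05), with a median of +0.45 (camera adjusted p = 3.92e-13, and adjusted p = 0.0514 with an estimated correlation). The regions of plasmid pMOL28, the chromosome and the chromid were not called (adjusted p = 0.884, 0.438 and 0.777). In the mutants 1086 regions changed in rpoIJK (719 higher, 367 lower), 709 in rpoQR (503 and 206), 942 in rpoPE cnrH (550 and 392) and 509 in rpoLMO (218 and 291). Counts fell to 458 in rpoQR without rpoQR replicate 3, and in rpoLMO to 317 without CH34 replicate 3 and 335 without CH34 replicate 2. In rpoIJK and rpoQR the chromid regions ranked higher than the rest in camera (adjusted p = 0.0123 and 0.0248) and those of the chromosome lower (adjusted p = 0.00412 and 0.0121), although the chromosome medians were +0.04 and +0.06. With an estimated correlation the chromosome calls held (adjusted p = 0.00478 and 0.00947) and the chromid calls did not (adjusted p = 0.164 and 0.171). None of these 4 calls held with cyclic loess (adjusted p = 0.131 and 0.178 for the chromid, 0.082 and 0.0812 for the chromosome), and the chromid mean in rpoQR turned to −0.10 with normexp without the speck. The chromid call in rpoQR was also lost without rpoQR replicate 3 (adjusted p = 0.0575). The pMOL28 regions ranked higher in rpoQR and rpoLMO (adjusted p = 0.0214 and 0.0312, and adjusted p = 0.171 and 0.277 with an estimated correlation), the former call lost with normexp (adjusted p = 0.0968) and the latter without CH34 replicate 1 or rpoLMO replicate 2 (adjusted p up to 0.112). The pMOL30 regions in rpoIJK and rpoQR and the pMOL28 regions in rpoIJK were not called (adjusted p = 0.0502, 0.0753 and 0.101), except pMOL30 without rpoIJK replicate 1 and without rpoQR replicate 2 (adjusted p = 0.0291 and 0.0486). No replicon was called in rpoPE cnrH (adjusted p from 0.0548 to 0.21), except pMOL28 without CH34 replicate 3 (adjusted p = 0.0404) and with both normexp corrections, cyclic loess and quantile normalization (adjusted p = 0.023, 0.0144, 0.0358 and 0.0302).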

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

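Normexp without the speck, cyclic loess, the array row, merged gene segments, removal of the 2 tag intervals, the series matrix numbering and the added lists were chosen after the data had been seen. Where a value moved, the cause was not tested, except that a stricter threshold calls fewer genes by construction and that normexp widens the pooled spread, as described below. Of the counts under settings that keep all replicates 256 stayed within 1.5 times the value reported and 42 did not, and of those that leave out 1 array 99 did and 9 did not. With all replicates, list calls were unchanged in 328 cases, gained in 20 and lost in 22, and in 2 more the sign of the mean turned with a call in 1 of the settings compared. Without 1 array they were unchanged in 100, gained in 6 and lost in 2. For named genes 4892 cases with all replicates kept direction and call, 254 lost the call (132 of them under normexp), 33 gained it and 5 turned in sign, and without 1 array 1919 kept it, 91 lost it and 3 gained it. Whether the replicate numbers pair the arrays stays open. Arrays of equal number had a mean correlation of 0.0944 and other pairs −0.0479, and 8 of 15 arrays had their best partner under the same number. With the series matrix numbering these values were −0.0321, 0.0154 and 3 of 15. Sorted by slide instead of number they were 0.0731, −0.0708 and 12 of 15. Replicate number and slide overlap in part, so these values cannot tell them apart. They are not correlations of the levels themselves, which were 0.961 to 0.986 within groups. With replicate as a block, which could not be fitted for the lone array, 2546, 1731, 2365 and 1496 genes were called in rpoIJK, rpoQR, rpoPE cnrH and rpoLMO, more than without the block. With the series matrix numbering the block gave 2318, 1467, 2103 and 1232, fewer than without it. Signal over background limits what can be said of dim genes, and the number of arrays limits the precision.

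With normexp the counts of genes against CH34 were 261, 42, 371 and 43 for rpoIJK, rpoQR, rpoPE cnrH and rpoLMO, and 133 for the metals. Against the other mutants they were 211, 26, 277 and 539, for intergenic regions 113, 11, 170, 10 and 24 in the order of the comparisons with CH34, and the overlap between mutants was 136. For rpoIJK, rpoPE cnrH, rpoLMO and the metals, both normexp corrections gave the same median changes (0.0048, −0.1081, −0.0099 and −0.09). Without the speck 1557, 1651, 759 and 424 genes were called there. That normexp called fewer genes than normexp without the speck in these comparisons thus came from the pooled spread, which rpoQR replicate 3 widened. The pooled spread of that array does not explain why normexp without the speck also called fewer than the 2398, 2215, 1351 and 582 genes reported. The directions of fliG and pgk__2 in rpoQR (+0.0074 and +0.0633) and proA with metals (−0.0526) reversed. With normexp without the speck the counts were 1557 genes for rpoIJK and 759 for rpoLMO, and 618, 437, 237 and 115 intergenic regions for rpoIJK, rpoQR, rpoLMO and the metals. There the ribosomal list in rpoQR (+0.0247, against −0.09 and no call as reported), gatC in rpoQR (−0.0765) and proA with metals (−0.0526) reversed, and with cyclic loess the ribosomal list in rpoPE cnrH (+0.0186), its call lost. The mean of that list also turned without a call in either setting, in rpoIJK with cyclic loess (+0.11) and in rpoQR with cyclic loess (+0.04) and quantile normalization (+0.00).

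Requiring signal above background on all 16 arrays gave 308 genes for rpoQR against the other mutants and 448 intergenic regions for rpoQR. Array row as a block gave 671 genes for rpoPE cnrH against the others. The series matrix gave 448 intergenic regions for rpoQR and 142 for the metals, and a model of only the compared groups gave 360 genes and 90 intergenic regions for the metals. Of 13 list calls over the 5 comparisons with CH34, 3 held with an estimated correlation (histidine in rpoIJK and rpoPE cnrH, flagellar with metals), and the lists assembled later gave 6 calls. With at least 2-fold change required, 871, 578, 858 and 444 genes were called for rpoIJK, rpoQR, rpoPE cnrH and rpoLMO against CH34, 441, 216, 441 and 942 against the other mutants, and 466, 306, 428 and 167 intergenic regions.

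Leaving out single arrays gave 991 (without rpoQR replicate 3) to 1464 genes for rpoQR, and 816 (without CH34 replicate 3) to 1095 for rpoLMO. For intergenic regions it gave 458 (without rpoQR replicate 3) to 669 for rpoQR and 317 (without CH34 replicate 3, and 335 without CH34 replicate 2) to 457 for rpoLMO. Against the other mutants it gave 960 (without rpoIJK replicate 2) to 1914 for rpoIJK, 285 (without rpoQR replicate 3, and 358 without rpoQR replicate 1) to 527 for rpoQR, and 757 (without rpoPE cnrH replicate 2) to 1262 for rpoPE cnrH. Counts that stayed within 1.5 times ran from 1899 to 2295 genes for rpoIJK, 1726 to 2041 for rpoPE cnrH, 484 to 539 for the metals, 2261 to 2891 for rpoLMO against the others and 1533 to 1722 for the overlap. The number of list calls ran from 12 to 15.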

Other observations

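Lists assembled from the symbols on the array, the tests on the stretches at background, the comparison with cyclic loess and the match of dim genes to the rpoPE cnrH run were chosen after the results had been seen. The slope on the share of probes above background, the spread over the run and the splits of the arrays were set beforehand.

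Citric acid cycle genes were lower in the rpoIJK deletion than in CH34, 7 of 7 falling (7 when adjusted over the list alone), with a mean of −0.84 (camera adjusted p = 0.000651, and adjusted p = 0.295 with an estimated correlation). The gene sucC changed by −1.14 ± 0.19 (adjusted p = 0.00051), gltA, for citrate synthase, by −0.95 ± 0.16 (adjusted p = 0.000544), kgd by −0.86 ± 0.16 (adjusted p = 0.000921) and sdhA, for a subunit of succinate dehydrogenase, by −0.83 ± 0.15 (adjusted p = 0.000755). Of all 304 genes with a symbol 104 were called lower and 29 higher in this comparison. Under the 5 other scalings the list mean lay between −1.06 and −0.61, and camera called it in each and without any 1 of the 6 arrays (adjusted p up to 0.00161). Against the other mutants the list was lower in rpoIJK as well, 7 of 7 falling with a mean of −0.54 (adjusted p = 0.00189, and adjusted p = 0.422 with an estimated correlation). In rpoPE cnrH the mean was −0.56 (adjusted p = 0.0392, and adjusted p = 0.557 with an estimated correlation), a call lost without CH34 replicate 3 or rpoPE cnrH replicate 1 (adjusted p up to 0.112) and with cyclic loess, quantile normalization and both normexp corrections (adjusted p = 0.178, 0.196, 0.354 and 0.203).

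The 3 measured cobalamin genes were all higher in rpoIJK than in CH34, cobS by 1.79 ± 0.36, cobD by 0.92 ± 0.17 and cobT by 0.51 ± 0.16 (adjusted p = 0.00156, 0.000796 and 0.0213), but the list was not called (adjusted p = 0.0648). Against the other mutants the same list was called with a mean of +0.93 (adjusted p = 0.0284, and adjusted p = 0.422 with an estimated correlation), a call lost without rpoIJK replicate 1 (adjusted p = 0.0685) and with normexp (adjusted p = 0.233). In rpoLMO, 11 of 16 translation factor and ribosome assembly genes were higher than in the other mutants (mean +0.42, adjusted p = 0.00262, and adjusted p = 0.317 with an estimated correlation), as were 6 of 8 protein export genes (mean +0.62, adjusted p = 0.00573, and adjusted p = 0.317 with an estimated correlation). The protein export call was lost with cyclic loess and quantile normalization (adjusted p = 0.0581 and 0.0584). In the same rpoLMO comparison 134 of all 304 genes with a symbol were called higher and 27 lower, so these lists moved with their class.

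The first pattern weighed is the loss of signal over the stretches of 74 and 22 tags in the rpoIJK, rpoQR and rpoLMO deletions. Inside the stretches 49 of the 79 features measured in CH34 were at background on all 9 arrays (1 of them in rpoPE cnrH too), against 0% of genes outside, matched for their CH34 level. The stretches were defined from such losses, so the share inside is no independent evidence, and each mutant's own share had to reach about 62.0%. Taken singly, the rpoIJK, rpoQR and rpoLMO deletions had 72.2%, 65.8% and 79.7% at background inside, against 0.138%, 0.0074% and 2.42% of matched genes outside. Dimmer arrays are argued against for rpoIJK and rpoQR, with 77.5% to 85.0% and 83.5% to 91.2% of probes above background, against 71.3% to 80.3% in CH34. The rpoLMO arrays were the dimmest of the 3 (70.1% to 71.4%), with 165 genes at background in all, against 63 in rpoIJK and 53 in rpoQR. For rpoLMO only the 2.42% outside bears on dimness, and it argues against dimness as the whole cause. A candidate explanation is that the DNA of these stretches is missing in the 3 strains, which stays open, since 12 of the 79 features stayed well above background on all 9 arrays, and no DNA was measured. Whether the probes of those 12 are specific to the stretches was not tested. Over the 79 features, the rank correlation of the CH34 levels was 0.19 with the mean of the 3 mutants and 0.63 with rpoPE cnrH. These correlations do not tell missing DNA from silent genes. No biological explanation was tested, and the effect of the deleted sigma factor genes on these tags remains open.

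The second pattern is a trend with brightness. The dimmest 10% of genes lay at medians of +0.57, +0.57 and +0.55 in rpoIJK, rpoQR and rpoPE cnrH and at −0.20 in rpoLMO, and the brightest 10% at −0.32, −0.18, −0.33 and +0.05. The share of probes well above background on each array gave 17.2% ± 11.4 of this tilt by its slope within groups, under the 50% set as the bound for a main cause. The trend as the whole cause of the counts is argued against as well, since after cyclic loess at least 70.7% of the genes called in each mutant were still called in the same direction. What made the trend stays open, and a difference between the strains is among the possible explanations, untested.

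The third pattern is the run of 57 tags that rose in rpoPE cnrH with a median of +4.82 (3.52 with the 23 tags at background in CH34 at their bound). Dim genes reading higher in this mutant are argued against, since genes outside the run with like CH34 levels had a median of 0.37. Whether extra copies of the region are the whole cause stays open. The changes of the 28 tags measurable in both groups ran from 0.52 to 7.02, and their standard deviation, 2.35, was 8.03 times their median standard error. That spread lies over the bound set beforehand but cannot decide, since some tags kept their signal where the stretch lost it. Rmet_1528, Rmet_1529 and Rmet_1530 rose by 2.09, 0.52 and 1.63, but stayed above background in rpoIJK, rpoQR and rpoLMO. In those mutants 12 tags of the stretch of 22 were at background, and these rose by 5.05 to 7.02 in rpoPE cnrH. Under other scalings the median of the run lay between 1.49 and 4.66. Whether the loss of rpoP, rpoE and cnrH raised these tags was not tested, nor was a change in DNA elsewhere in this strain.

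For each mutant against CH34 the 6 arrays allow 10 splits, too few for a share under 0.05. In 1 of 10 splits, the real one, as many genes were called, namely 2398, 1570, 2215 and 1351 in rpoIJK, rpoQR, rpoPE cnrH and rpoLMO, against at most 0, 0, 1 and 1 in another split. For intergenic regions it was again 1 of 10, with 1086, 709, 942 and 509 regions against at most 0, 1, 0 and 0. Lists were called as often in 5, 3, 3 and 7 of 10 splits, with 2, 3, 4 and 1 called in the real split and up to 4, 3, 4 and 3 in another. Against the other mutants, 1 of 100 regroupings of the 12 mutant arrays gave as many genes for rpoIJK (1785, highest other 109), 1 for rpoQR (546, highest other 65) and 1 for rpoLMO (2816, highest other 473). For rpoPE cnrH it was 2 of 100 (1141, highest other 2123). The regrouping with 2123 sets the 3 rpoLMO arrays against the rest, and the one with 473 the 3 rpoPE cnrH arrays, so both follow a structure of the samples. These 2 strains also lie in different array rows, and with row as a block the counts were 1928 for rpoLMO and 671 for rpoPE cnrH. For the overlap between mutants 1 of 100 regroupings of the 15 arrays with metals gave as many genes (2073, highest other 6). The shares of 1 or 2 in 100 regroupings argue against a grouping of the arrays unrelated to strain for these 5 counts. Regroupings that put arrays of different strains together widen the spread, so any strain difference favours the real grouping. The overlap was not tested against the sharing of the CH34 arrays. These shares do not exclude chance differences between single cultures, since the labels leave open whether the arrays of a strain came from separate cultures.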
